A study of Rubus occidentalis with 14 samples.

How the data were processed

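Poly(A) RNA from black raspberry (Rubus occidentalis) fruit was sequenced at 5 fruit stages, numbered 1 to 5 in the labels. Stages 1, 2, 3 and 5 had 3 libraries each and stage 4 had 2, giving 14 libraries, which the labels call biological replicates without saying how fruits or plants were divided among them. P-values therefore measure the spread between these libraries, part of which may be technical. Per the labels' protocols, the plants were a breeding selection grown at a research station, and RNA passing an integrity threshold was selected on poly(A) and made into libraries with a stranded kit. Per the submitters' processing notes, Trimmomatic (read trimming), HISAT2 (alignment) and DESeq2 (normalization) were used. Their versions, the read counter, the genome build and the annotation are not given in the sources used here.

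The deposited table held 1 normalised value per gene and library for 33253 gene identifiers. The deposited values are a normalised signal: the authors divided each gene's read count by 1 size factor per library. Within every library 100% of the values were whole multiples of the value of 1 read, to within 0.01 read, so the whole read counts behind the deposited values could be recovered. The medians of the log ratios of each library to the geometric mean of the genes with reads in all 14 libraries were equal, as median-of-ratios scaling gives. Every column of the table belonged to 1 of the 14 libraries and was matched by its library name.

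Recovered totals ranged from 7576338 to 39938265 reads per library, a 5.27-fold span, and size factors from 0.362 to 3.14. The value of 1 read therefore ranged from 0.319 to 2.76 normalised counts, and low levels were measured most coarsely in the shallow libraries. Bounds and intervals given for genes with few reads cover counting error only. A level with no reads was bounded by a floor of 3 reads per library. Replicate pairs within a stage differed well beyond counting noise (chi-square per gene 12.1 to 140.6), so no library was treated as a duplicate.

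The table gives gene identifiers only, and no reference annotation was used here. Gene lists for pigment synthesis, cell wall, photosynthesis, sugars, hormones, DNA methylation, seed, vascular and flower markers and other themes had been fixed as patterns on gene names before the data were examined. They could not be matched to identifiers, so no list was tested. For the same reason genomic coordinates and any check of gene length or GC content are not given.

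Genes were kept when at least 2 libraries reached 10 normalised counts, which left 19234 genes and set aside 14019, of which 7378 had no reads in any library. Values were tested as log2(normalised count + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and all 14 libraries in one model. The 5 stages thus shared one estimate of spread per gene. A moderated F test covered the 5 stages, and contrasts covered each pair of neighbouring stages and stage 1 against stage 5. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with calls at an adjusted p below 0.05. Fold changes on this scale understate the change of genes with low values.

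Genes named in the text were chosen by a rule set before the data were examined. They had to pass the test, with every library of the higher stage above every library of the lower stage and a mean of at least 100 normalised counts in the higher stage. Because only identifiers were given, the 2 largest rises and the 2 largest falls per comparison are named. Genes named outside this rule are said to be so.

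The procedure was tested on simulated counts with the real means and library sizes, in which 200 genes were changed. The changed genes were drawn from genes above a minimum mean, and each gene had the spread typical of its level. Most steps of the real data called far more than 200 genes, so the recoveries hold for the simulated setting only. For stage 1 to stage 2 (18508 simulated genes tested) it recovered 49% of 2-fold and 96% of 4-fold changes. For stage 2 to stage 3 (18490 genes) it recovered 49% and 99%, and for stage 3 to stage 4 (18503 genes) 33% and 97%. For stage 4 to stage 5 (18501 genes) it recovered 36% and 94%, and for stage 1 to stage 5 (18501 genes) 52% and 97%. Unchanged genes made up 2.03% to 10.3% of the calls.

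Alternatives were other pseudocounts (0.5 and 10), no filter or a minimum of 50, and upper-quartile and quantile scaling. Others were a flat prior variance, a replicate block, a term for library names, leaving out each library, and fitting only the 2 stages compared. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Scaling to equal total reads and a term for the letters of the title codes were added after the data had been seen. In stages 1, 2, 3 and 5, replicates 2 and 3 shared a code in their titles that replicate 1 did not have. The codes of stage 3 replicates 2 and 3 and of stage 4 replicate 2 open with TH and all others with YH, and the meaning of these letters is not given in the sources used here. In stage 4 the numbers in the titles (1 and 2) differ from those in the library names (2 and 3). Title numbers are used throughout. Libraries of stages 1 and 2 with the same replicate number deviated together from their stage means (correlations across genes of 0.39, 0.236 and 0.235 for replicates 1, 2 and 3), so these numbers were taken to pair the 2 stages, from the data alone. No other pair of stages had every same-numbered pair above 0.1.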

Results

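Fruit transcriptomes of black raspberry were compared over 5 stages to follow how gene activity changed through ripening. The data were 14 poly(A) RNA-seq libraries of fruit, 3 each for stages 1, 2, 3 and 5 and 2 for stage 4. Replicates 1, 2 and 3 held 35199548, 7576338 and 35168553 reads in stage 1 and 30430672, 8601064 and 39938265 reads in stage 2. In stage 3 they held 34512921, 8597118 and 10610577 reads, and in stage 5 28529382, 9913885 and 18482104 reads. The stage 4 replicates held 9897285 and 29226270 reads. Of 33253 genes in the table, 19234 were expressed highly enough to be tested.

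Reads became concentrated in fewer genes from stage to stage. The 10 most abundant genes of a library took 3.80% ± 0.30 of its reads in stage 1 (SD, n = 3) and 7.80% ± 0.30 in stage 2 (n = 3). Their share was 9.45% ± 0.68 in stage 3 (n = 3), 10.9% ± 0.22 in stage 4 (n = 2) and 16.5% ± 1.09 in stage 5 (n = 3). The 100 most abundant genes went from 13.6% ± 1.01 in stage 1 to 38.2% ± 1.02 in stage 5. Every stage 5 library lay above every stage 1 library, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The sum of the deposited normalised counts rose with it, from 11371990 ± 236974 in stage 1 to 27552453 ± 336358 in stage 5 (SD, n = 3 each). Changes reported here are relative to the deposited scaling, under which the median log2 change of all genes was -0.06 from stage 1 to stage 2, -0.12 from stage 2 to stage 3, 0 from stage 3 to stage 4, -0.0043 from stage 4 to stage 5 and -0.30 from stage 1 to stage 5. With scaling to equal total reads, a choice made after the data were seen, these medians were -0.31, -0.70, -0.21, -0.18 and -1.54. After quantile normalization they were 0.17, -0.01, 0.0036, 0.04 and 0.09.

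**Figure D1:**
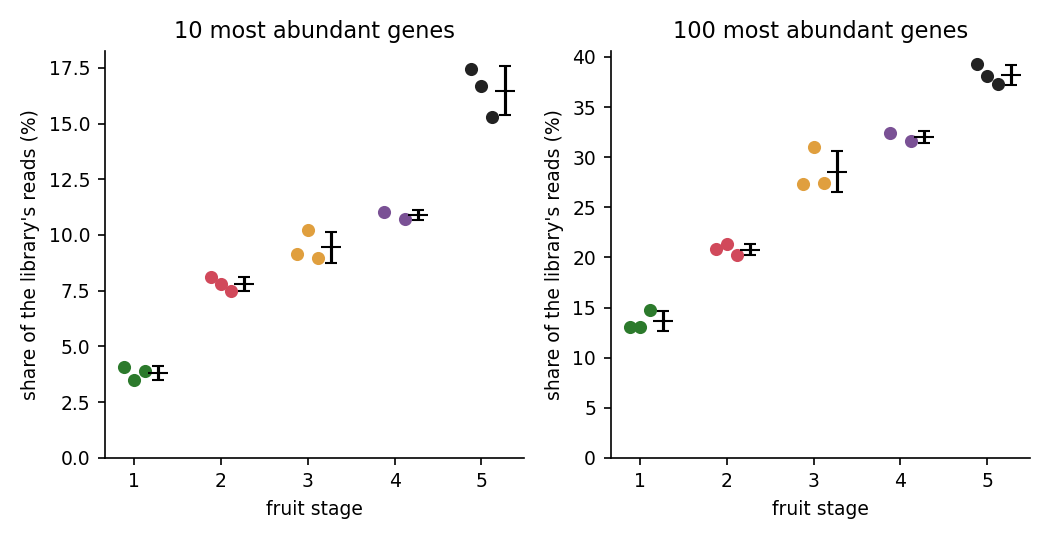
Share of each library's reads (y axis, percent) taken by its 10 (left) or 100 (right) most abundant genes, by fruit stage (x axis). Points are libraries and black marks are the mean ± SD; the mean share of the 10 most abundant genes went from 3.80% in stage 1 to 16.5% in stage 5.

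Libraries grouped by stage. Replicates of a stage correlated at a mean Pearson r across genes of 0.969 to 0.982, and stage 1 against stage 5 at 0.663; genes are not independent replicates, and these values describe the libraries only. Neighbouring stages correlated at 0.799 (1 and 2), 0.908 (2 and 3), 0.974 (3 and 4) and 0.954 (4 and 5), so stages 3 and 4 were about as alike as replicates of one stage. The leading principal component held 68.8% of the variance and ordered the stages from 1 to 5, and the next held 13.7% and set stage 2 apart from stages 1 and 5. Stage 2 replicate 2 correlated with the stage 3 libraries at 0.923 to 0.938, against 0.884 to 0.904 for the other 2 stage 2 libraries.

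**Figure D2:**
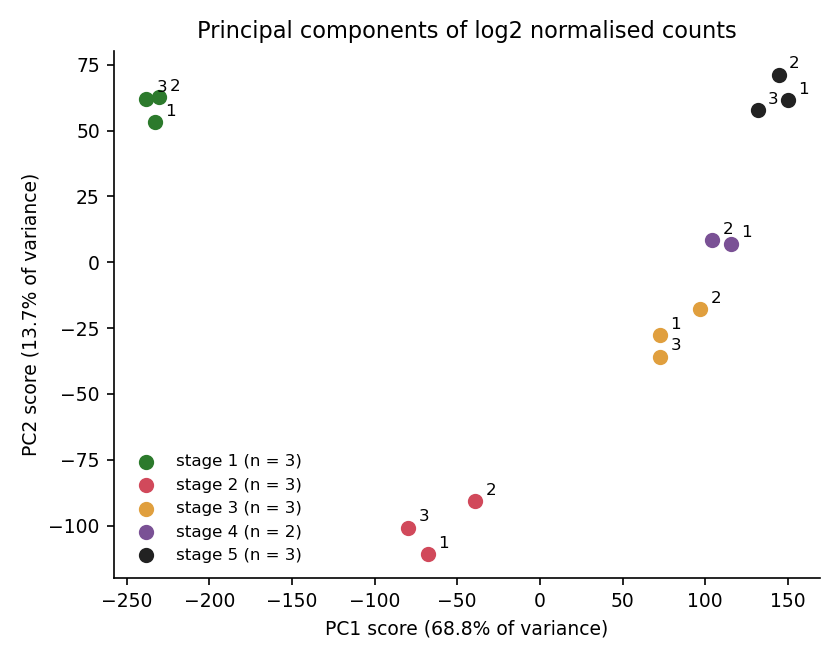
Scores of the 14 libraries on the first (x axis) and second (y axis) principal components of log2 normalised counts over 19234 genes; colours are stages and digits are replicate numbers. Stages run from left to right, stage 2 lies lowest, and stages 3 and 4 lie side by side.

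Most expressed genes changed over the 5 stages. The F test called 16591 of 19234 genes (86.3%, adjusted p below 0.05), and 13568 of these differed by at least 1 on the log2 scale between their highest and lowest stage means. Of the called genes, 6879 (41.5%) had their highest mean in stage 1, 2484 (14.97%) in stage 2, 957 (5.77%) in stage 3, 2234 (13.5%) in stage 4 and 4037 (24.3%) in stage 5. The stage means of 1846 genes rose at each of the 4 steps and those of 2044 fell at each, 11.1% and 12.3% of the called genes, where a random order of the stages would give 0.83% each. These counts use the order of the means only. Genes called upwards at all 4 steps numbered 0, as did those called downwards at all 4, and the step from stage 3 to stage 4 called 3 genes in all. With equal total reads the F test called 17552 genes, of which 11264 peaked in stage 1, 934 in stage 4 and 1123 in stage 5.

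Stage 1 and stage 5, the ends of the series, differed in most genes. From stage 1 to stage 5, 6415 genes rose and 8626 fell, 15041 of 19234 tested (78.2%). The change reached at least 4 on the log2 scale in 518 rising and 2321 falling genes. Among genes meeting the rule for named genes, the largest rise as deposited was in Ro06_G29120. It went from 308 ± 154 normalised counts in stage 1 to 594737 ± 87106 in stage 5 (SD, n = 3 each). This was a log2 change of 11.04 ± 0.69 (SE) with a limma adjusted p of 1.4e-08. Ro03_G07437 rose from 133 ± 74.1 to 226213 ± 16531 (log2 change 10.94 ± 0.95, adjusted p 2.36e-07). Ro06_G09850 was at 974 ± 12.5 in stage 1 and had no reads in any stage 5 library, at least 187-fold lower against a floor of 3 reads per library (adjusted p 1.68e-08). Ro04_G00307 fell from 12131 ± 1532 to 30.8 ± 31.04 (log2 change -9.91 ± 1.22, adjusted p 6.09e-06), a 394-fold difference of means. Its log2 change was -8.08, -10.57 and -11.07 without stage 5 replicate 1, 2 and 3, and -8.65 by edgeR and -8.63 by DESeq2. That of Ro03_G07437 was 10.32 without stage 1 replicate 1, and DESeq2 gave no adjusted p for this gene. Ro03_G07437 rose more than Ro06_G29120 after quantile normalization (10.35 against 9.66) and without stage 1 replicate 3 (11.22 against 11.15). No function is assigned to these genes here, because the table pairs no names with its identifiers. Among genes with a mean of at least 100 normalised counts in one of these 2 stages, 89 present in stage 1 had no reads in any stage 5 library and 4 present in stage 5 had none in any stage 1 library. These 2 counts were not matched for depth. The mean size factor was 2.28 in stage 1 and 0.687 in stage 5, so a low level was more easily missed in stage 5. The share of called genes that rose was 42.7% as deposited, 52.8% after quantile normalization and 14.2% with equal total reads, so the balance of rises and falls depended on the scaling.

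**Figure D3:**
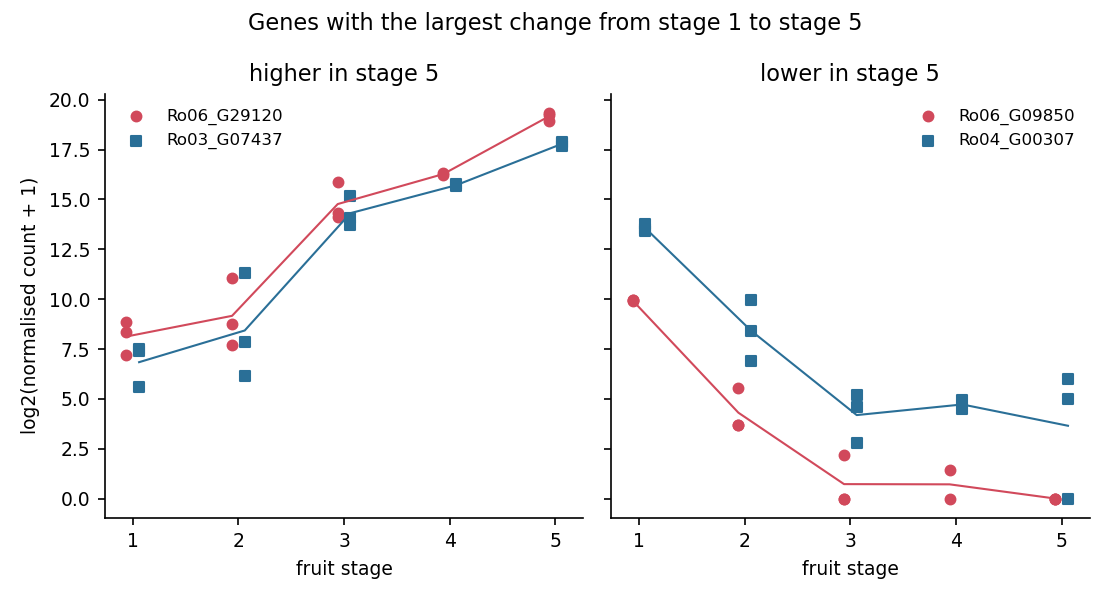
Level of the 2 genes with the largest rise (left) and the 2 with the largest fall (right) from stage 1 to stage 5 among genes meeting the rule for named genes. The y axis is log2(normalised count + 1) and the x axis is fruit stage. Points are libraries and lines join stage means; Ro06_G29120 and Ro03_G07437 climb mainly after stage 2, while Ro06_G09850 and Ro04_G00307 drop mainly between stages 1 and 3.

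From stage 1 to stage 2, the earliest step, 3568 genes rose and 4665 fell (8233 called, 42.8% of those tested). Large falls outnumbered large rises: 833 genes fell and 160 rose by at least 4 on the log2 scale. Ro02_G35251 rose from 2.03 ± 2.96 to 1872 ± 834 normalised counts (n = 3 each, log2 change 9.64 ± 0.82, adjusted p 8.43e-07). Its mean was lower again in the later stages, 458 ± 265 in stage 3 and 343 ± 285 in stage 5. Ro03_G32054 had a similar course, from 1.84 ± 1.61 to 1726 ± 217 (log2 change 9.47 ± 0.66, adjusted p 1.86e-07), with 236 ± 216 in stage 5. Ro01_G29653 fell from 28261 ± 16254 to 37.7 ± 23.1 (log2 change -9.60 ± 1.79, adjusted p 0.000704). Ro02_G08807 fell from 2622 ± 895 to 2.59 ± 1.21 (log2 change -9.51 ± 0.82, adjusted p 9.8e-07). Leaving out single libraries moved the fold change of 3 of these genes by over 1.5-fold, with all 3 still called. The log2 change was 10.42 for Ro02_G35251 without stage 1 replicate 1 and 8.84 for Ro03_G32054 without stage 1 replicate 2. For Ro01_G29653 it was -8.91 without stage 2 replicate 1. The share of called genes that rose was 43.3% as deposited, 56.4% after quantile normalization and 26.6% with equal total reads. Without stage 2 replicate 2, the library nearest to stage 3, 7112 genes were called. Leaving out any other single library of these 2 stages gave 7061 to 7881. The values above come from a test without the pairing of these stages by replicate number. With a replicate block over all 14 libraries, which applies the numbers to stages 3 to 5 as well, 8637 genes were called. Of these, 8100 were shared with the 8233, and the genes named for this step stayed called. A block for stages 1 and 2 alone was not fitted.

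As deposited, the step from stage 2 to stage 3 called the most genes of the 4 steps between neighbours: 4502 rose and 5556 fell (10058, 52.3% of those tested). This ranking depended on the setting. After quantile normalization the step from stage 1 to stage 2 called 9916 genes and this step 8388. With the letters of the title codes as a term they called 8025 and 7340. Large changes were rarer than at the step before, 93 rises and 87 falls of at least 4 on the log2 scale. Ro07_G33307 rose by 6.98 ± 1.37 on the log2 scale (adjusted p 0.000997), to 10020 ± 3420 normalised counts in stage 3, and Ro05_G31334 by 6.37 ± 1.03 (adjusted p 0.00026), to 56744 ± 23637. The stage 2 libraries were far apart for both: Ro07_G33307 stood at 5.15, 1569 and 45.2 in replicates 1, 2 and 3, and Ro05_G31334 at 105.2, 6517 and 395. The stage 3 means were 18.6-fold and 24.3-fold those of stage 2. Without stage 2 replicate 2 the log2 changes were 9.16 and 8.04, without replicate 1 they were 5.17 and 5.07, and by edgeR 4.29 and 4.64, with both genes called each time; DESeq2 gave no adjusted p for either. Ro07_G17284 fell from 173 ± 44.9 to 1.21 ± 1.05 (log2 change -6.42 ± 0.61, adjusted p 1.28e-05), and Ro06_G25194 from 157 ± 37.2 to 3.76 ± 6.50 (log2 change -6.06 ± 0.79, adjusted p 6.03e-05). The latter change was -5.46, -5.46 and -7.27 without stage 3 replicate 1, 2 and 3. Without stage 2 replicate 2, 9427 genes were called, against 8562 without stage 2 replicate 1 and 8108 without stage 2 replicate 3. The share of called genes that rose was 44.8% as deposited and 15.1% with equal total reads.

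From stage 3 to stage 4 almost no gene passed the test. By limma 3 genes rose and 0 fell, although 2626 genes had an unadjusted p below 0.05, where 962 are expected by chance. Ro05_G12164 rose from 443 ± 179 (n = 3) to 2757 ± 425 normalised counts (n = 2), a log2 change of 2.72 ± 0.37 with an adjusted p of 0.0385. It reached 15024 ± 5700 in stage 5. Ro07_G09021 rose from 313 ± 47.0 to 1236 ± 263 (log2 change 1.97 ± 0.25, adjusted p 0.0247) and stood at 1301 ± 156 in stage 5. The third, Ro07_G04726, lies below the level set for named genes, was named after its values were seen, and rose by 3.13 ± 0.37 (adjusted p 0.0236). The edgeR quasi-likelihood test called 2 genes and DESeq2 called 315, with 152 rising and 163 falling. The count rested on single libraries: it was 368 without stage 3 replicate 2, 37 without stage 4 replicate 2 and 0 by limma without stage 3 replicate 3 (1780 genes at an unadjusted p below 0.05). It was 8 without stage 3 replicate 1, 6 or 1 without stage 2 replicate 2 or 3, 5 without stage 4 replicate 1, and 11 or 10 without stage 5 replicate 2 or 3. Leaving out a stage 4 library leaves 1, assumed to vary like the other stages. Ro05_G12164 was no longer called (adjusted p 0.0549 to 0.104, log2 change 2.33 to 2.88) without stage 1 replicate 2 or 3, stage 2 replicate 3, stage 3 replicate 3, either stage 4 replicate or stage 5 replicate 1. Ro07_G09021 was no longer called (adjusted p 0.0524 to 0.077, log2 change 1.75 to 2.19) without stage 2 replicate 3, stage 3 replicate 3 or either stage 4 replicate. Neither gene was called with only the libraries of these 2 stages (adjusted p 0.391 for Ro05_G12164 and 0.356 for Ro07_G09021, log2 change 2.72 and 1.97) or after quantile normalization (0.12 and 0.147, log2 change 2.37 and 1.70), and Ro05_G12164 was not called with a flat prior variance (0.0531). With a term for libraries named br1, which stage 4 lacks, limma called 0 genes (2733 at an unadjusted p below 0.05), with log2 changes of 2.63 (adjusted p 0.0743) for Ro05_G12164 and 1.90 (0.0553) for Ro07_G09021. Stage 3 replicates 2 and 3 and stage 4 replicate 2 have title codes that open with other letters than those of the remaining libraries. With these letters as a term, chosen after the data were seen, limma called 0 genes (2486 at an unadjusted p below 0.05), with log2 changes of 2.70 (adjusted p 0.0917) and 2.00 (0.0578). Among the libraries of these 2 stages that carry those letters (2 against 1) limma called 0 genes (1420 at an unadjusted p below 0.05), with log2 changes of 3.03 and 2.20, and among the others (1 against 1) 0 genes (2052), with 2.26 and 1.73, the other stages supplying the spread. With equal total reads 21 genes were called, of which 28.6% rose.

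From stage 4 to stage 5, the last step, 1473 genes rose and 2075 fell (3548 called, 18.4% of those tested). Ro06_G09727 rose from 11.1 ± 1.41 (n = 2) to 579 ± 133 normalised counts (n = 3), a log2 change of 5.56 ± 0.80 with an adjusted p of 0.000478. Ro01_G29570 rose from 15.99 ± 4.75 to 774 ± 75.7 (log2 change 5.54 ± 0.58, adjusted p 4.05e-05). Ro03_G06304 fell from 206 ± 48.2 to a level of 3 reads over all of stage 5, each in replicate 3 (limma adjusted p 9.08e-06). Its reads pooled within each stage, over the summed size factors, gave a ratio of 153 with a 95% exact Poisson interval of 52.2 to 740. Ro03_G26880 fell from 143 ± 10.2 to 1 read over all of stage 5 (limma adjusted p 2.69e-06). Its ratio from pooled reads was 287, with an interval of 51.5 to 11333. Both of these genes had been between 101 and 290 normalised counts in the means of stages 1 to 4. Leaving stage 4 with 1 library lowered the count to 1785 (without replicate 1) or 1720 (without replicate 2), with the lone library assumed to vary like the other stages. The count was 1456 with only the libraries of these 2 stages and 2099 after quantile normalization. The log2 change of Ro06_G09727 was 6.37 with the letters of the title codes as a term. The share of called genes that rose was 41.5% as deposited and 21.04% with equal total reads.

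**Figure D4:**
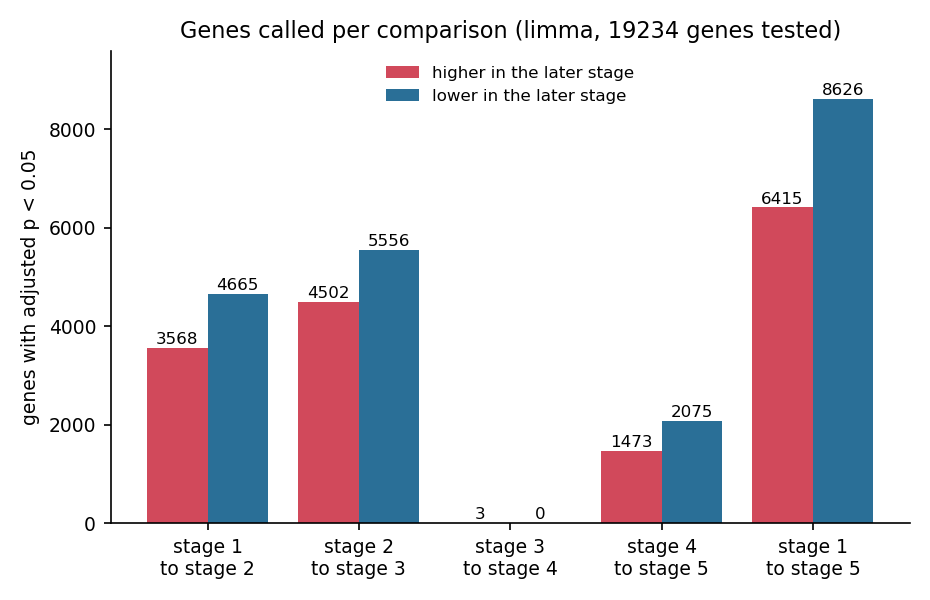
Number of genes with a limma adjusted p below 0.05 (y axis) that were higher (red) or lower (blue) in the later stage, for the 4 steps between neighbouring stages and for stage 1 to stage 5 (x axis). Digits on the bars are the counts, and the step from stage 3 to stage 4 holds 3 genes. As deposited, the step from stage 2 to stage 3 holds the most of the 4 steps. With quantile normalization or the letters of the title codes as a term, the step from stage 1 to stage 2 did.

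The steps also differed in the size of change over all genes. The root mean square of the log2 changes, after the mean squared SE was subtracted from their mean square, was 1.68 from stage 1 to stage 2, 1.27 from stage 2 to stage 3, 0.38 from stage 3 to stage 4 and 0.81 from stage 4 to stage 5. From stage 1 to stage 5 it was 2.72. Of the 19234 genes, 8573 were called at 1 step only, 6109 at 2 or more and 4552 at none, and 2334 were called upwards at one step and downwards at another.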

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

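Equal total reads and the term for the letters of the title codes were chosen after seeing the data. The counts over the 5 stages and from stage 1 to stage 5 stayed within 1.5 times their values under every setting run. The genes and directions behind them were less stable. Of the 15041 calls from stage 1 to stage 5, equal total reads kept 12838, with 10937 in the same direction. Quantile normalization kept 11425, with 11010 in the same direction. Requiring a log2 change of at least 1 lowered the calls to 5262 (stage 1 to 2), 6074 (stage 2 to 3) and 1971 (stage 4 to 5). From stage 3 to stage 4 the 3 calls became 10 with a pseudocount of 10, 6 without a filter, 7 with a minimum of 50, 1 with quantile normalization, 21 with equal total reads, 10 with a flat prior variance and 0 with the letters of the title codes as a term (2486 genes at an unadjusted p below 0.05). They became 315 with DESeq2 (which gave no adjusted p for 4509 genes) and 0 with only the 2 stages' libraries (2388 genes at an unadjusted p below 0.05), and ranged from 0 to 368 when single libraries were left out. From stage 4 to stage 5 the calls were 2099 with quantile normalization, 1456 with only the 2 stages' libraries, and 1720 to 3743 when single libraries were left out. Equal total reads moved the genes peaking in stages 1, 4 and 5 to 11264, 934 and 1123, out of 17552 called by the F test under that scaling. The cause of the other moves was not tested. Beyond stages 1 and 2, the pairing of libraries by replicate number was not settled: over all stages same-numbered libraries correlated at -0.088 to 0.39, with 9 of 26 pairs over 0.1, and 11 of 14 libraries correlated best with their own number, a hint from the data. The replicate block gave 8637 calls from stage 1 to stage 2 (8817 with library name numbers) and left 0 calls from stage 3 to stage 4 (2795 genes at an unadjusted p below 0.05; 2828 with library name numbers, and 2733 with a term for br1 libraries, also 0 calls) and changed no other count of calls by over 1.5 times. Of 18 named fold changes, 13 moved by over 1.5-fold with quantile normalization, 11 with a pseudocount of 10 and 6 with equal total reads. The edgeR test moved 5 by as much, and a pseudocount of 0.5 moved 4. No named gene reversed in 519 checks, which for DESeq2 covered only the 15 of 18 with an adjusted p. These genes had been chosen for their large changes in the same data, so a reversal was unlikely from the start. In 24 checks a call was lost, all of Ro05_G12164 and Ro07_G09021 from stage 3 to stage 4. The planned gene list alternatives were not run, since no list could be matched. Shallow libraries, where 1 read was worth up to 2.76 normalised counts, limit what can be said of low genes.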

Other observations

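The comparison of abundant genes, the counts of genes higher or lower in a middle stage and the position of stage 3 replicate 2 between stages 3 and 4 were chosen after the data had been seen, as was the interval given for the interquartile range of early rising genes. The list of the most abundant transcripts changed as the fruit moved through the stages. None of the 10 most abundant genes of stage 1 was among the 10 of stage 5, while stages 3 and 4 shared 9 of 10. The 10 leading genes of stage 5 took 0.228% ± 0.064 of the reads in stage 1, 3.14% ± 0.65 in stage 2, 6.83% ± 1.22 in stage 3, 9.20% ± 0.28 in stage 4 and 16.4% ± 1.03 in stage 5 (SD, n = 3, 2 in stage 4). The following identifiers, chosen after their values were seen, led these lists. Ro03_G20665 had the highest mean share in stage 1, 0.604% ± 0.24. Its share was higher in stage 2, 1.45% ± 0.37, and 0.469% ± 0.15 in stage 5. Ro04_G00194 was the most abundant gene of stages 2, 3 and 4, going from 0.0607% ± 0.031 of reads in stage 1 to 1.92% ± 0.21 in stage 2 and 2.34% ± 0.30 in stage 5. Ro06_G22021 led stage 5 with 3.11% ± 0.31, against 0.0191% ± 0.014 in stage 1 and 0.77% ± 0.062 in stage 4.

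Some genes turned at stage 2. Both of its steps called 637 genes that were higher in stage 2 than in stages 1 and 3, and 645 that were lower than in both. Independent lists of these lengths would share 1031 and 1092, so genes that reversed at stage 2 were fewer than independent steps would give. At most 0 genes were shared in 20 simulations of unchanged stages, in which few genes can be called at all, so that value is no measure of an excess. The 3 stage 2 libraries were not divided between the steps, since this would leave 1 of the steps with fewer than 2 of them, and the overlap includes what sharing them adds. Without stage 2 replicate 2 the counts were 513 and 759. At stage 3 the counts were 0 and 1, and at stage 4 0 and 0, where the step from stage 3 to stage 4 called few genes.

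Stage 2 replicate 2 lay 0.264 of the way from the other stage 2 libraries to stage 3. Its lower depth is argued against, since thinning the other stage 2 libraries to its 8601064 reads moved them by at most 0.0033. A sample moved evenly on the log scale is argued against too: the 80 genes that rise most towards stage 3 stood at 0.709 of the way and the 74 that fall most at 0.0893, a difference of -0.62. A share of stage 3 material was put at 32.3% (30.4% to 39.5% over 6 choices of reference libraries) from rising genes. From falling genes it was 27.2% (19.97% to 35.0%), a difference of -5.14 points within that range. The range is wide because the falling genes depended on the stage 2 reference. With replicate 1 as reference, rising genes gave 31.6% to 39.5% and falling genes 19.97% to 20.3%. With replicate 3 they gave 30.4% to 38.5% and 34.1% to 35.0%. The 2 sets came close only with replicate 3, so the test does not settle the question. A pool of riper and less ripe fruit or mixing of RNA or libraries stays a candidate explanation. Early induction of the rising genes, each to its own extent, called for a wider spread of their ratios to stage 3 than in any stage 3 library, and their interquartile range of 1.05 (log2) lay below the highest of these, 1.18; the difference of -0.12 had a 95% interval of -0.55 to 0.22 over 10000 resamplings of genes, so the test did not decide.

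The scarcity of calls from stage 3 to stage 4 is not explained by 2 libraries in stage 4 alone: with 2 libraries in each stage, the other steps called at least 2854 genes, and this step 0 to 368. Stage 3 replicate 2 stood 0.554 of the way from the other stage 3 libraries to stage 4, against 0.345 and 0.226 for replicates 1 and 3, and stage 4 replicates 1 and 2 stood 0.403 and 0.600 of the way to stage 3. Simulated stages with no difference gave 0.502 (0.474 to 0.527) for a stage 3 and 0.748 (0.718 to 0.774) for a stage 4 library. These are means and ranges over 20 draws, and noise alone moves a library along so short an axis. Stage 3 replicate 2 lay above its range, and the other libraries of both stages lay below theirs. The draws gave each gene independent noise, so they leave out variation that genes share. Leaving out stage 3 replicate 2 gave 368 calls and leaving out stage 4 replicate 2 gave 37, but the positions do not tell whether either library lies out of place. A small biological difference between these stages stays open beside it, and the step remained the smallest of the 4 in calls under every choice of 2 libraries.

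Fewer genes had reads at later stages. Thinned to 7500000 reads, stage 1 libraries had reads on 21575 ± 91.5 genes and stage 5 libraries on 17828 ± 88.8 (SD, n = 3 each, two-sided exact permutation p 0.1, the smallest that 3 against 3 allow). The difference of 3748 genes after thinning argues against depth. Leaving out the 282 genes among the 100 most abundant of any library and thinning the rest to 5200000 reads left a difference of 3160 genes, so reads taken by abundant genes are not the whole of it. A loss of transcripts of many genes as fruit moves from stage 1 to stage 5 stays open as a hypothesis, found and tested on the same libraries.

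Chance was set against other groupings of the libraries. Over the 5 stages, 1 of 100 groupings (the real one) called as many as 16591 genes and the highest other called 7887. This makes chance unlikely but does not exclude it. Groupings that mix stages also widen the spread within groups, which lowers their counts. With 3 against 3 libraries the 10 splits are too few for a share below 0.05. The real split, 1 of 10 each time, called 8233 genes from stage 1 to stage 2, 10058 from stage 2 to stage 3 and 15041 from stage 1 to stage 5, and the highest other called 0 in each, the splits of stages 1 and 2 that part as many replicate pairs included.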
